A study of Mus musculus with 8 samples.

How the data were processed

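RNA from 8 organoid samples, 4 at day 7 and 4 at day 20 after tamoxifen, was labelled with biotin and hybridised to Illumina mouse beadchips, per the labels' protocols. The deposited values are log2 intensities. The authors' software, background correction and normalization method are not given in the sources used here. The distribution is the same on every array (median 6.81, maximum 15.43), as quantile normalization leaves it, and values are rounded to 2 decimals. The lowest values lie near 6.45 and not near 0, so intensities were not background-subtracted to 0, and fold changes of dim genes are compressed.

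A second deposited table of non-normalized values was not used: its 16 per-sample columns carry names that match no sample label, and columns were not assigned by order or by values. The planned starting point, normexp background correction with detection p-values from that table, was therefore replaced by the deposited log2 values, and a background limit took the place of detection p-values. The limit was the mode of all values, 6.7, plus the normal deviate for an upper-tail probability of 0.05 times 0.05837, the SD about the mode of the values at or below it, which gave 6.796; a strict limit at a probability of 0.01 was 6.836.

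Probes were named through the platform annotation: 34885 of 45281 had 1 gene symbol, 18 had several and 10378 were not listed there and are unnamed here. The entrez number of 34807 probes was found in the RefSeq table of mouse assembly GRCm38.p6, used for names only, and 0 symbols needed an update. No genome build is named for the array values, so no coordinates are given. Each of 19057 genes was represented by its probe with the highest mean over all 8 arrays, and 12466 genes above the limit on at least 4 of 8 arrays were tested. Folds against a group in which no probe of the gene exceeded the limit on any array are lower bounds against the higher of the limit and the probe's own value.

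Differences, day 20 minus day 7, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust variance, no covariates, two-sided, Benjamini-Hochberg adjusted p under 0.05). Before the data were examined, 34 gene lists were fixed, and all had at least 4 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry (which asks whether a list's genes move, on balance, one way) as alternatives. With an estimated correlation the enteroendocrine and inflammatory lists of the 10 called kept the call and 8 lost it. A list score is the mean over tested members of log2 intensity centred on each gene's mean, compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

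Genes named were set by a rule fixed at the same time: a panel of intestinal markers, the 12 largest rises and 12 largest falls among changed genes with non-overlapping groups and a proper gene name, and up to 4 members of each list described with the smallest adjusted p. Mki67 and Ly6a of the panel had no named probe. The identity of a few genes given by array value was chosen after their values were seen, and this is said there.

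On simulated data with the spread of the 12466 tested genes (10 simulations, 200 changed genes each), limma recovered 57.4% of genes changed by 0.5 on the log2 scale, 88% at 1, 98.2% at 2 and 100% at 4, and 6.06% of its calls were false. For the lists, camera called 100% of simulated lists of 20 genes shifted by 0.5, and 0.6% of unshifted lists had an unadjusted p under 0.05; simulated genes were independent, which real list members are not.

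Alternatives were replicate number as a block, cyclic loess, no filter and a strict filter, averaged probes, trend with robust variance, array weights, a 2-fold and a 1.2-fold requirement, and each array left out. Averages took in every probe of a gene above the limit on at least 4 arrays, also dim ones with compressed changes. Chosen after the data were seen were subtraction of the background mode with an offset of 16, and the 6 arrays with Xist signal alone. Arrays carry no counts, so depth has no equivalent here; their number and the signal over background limit precision.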

Results

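Gene expression was measured in intestinal organoids, 3-dimensional epithelial cultures that grow from crypts and normally hold stem, Paneth, goblet, enteroendocrine and absorptive cells. The mice carried floxed Apc alleles and a tamoxifen-inducible Cre expressed from the stem cell gene Lgr5. Apc restrains Wnt signalling, and organoids that lack it can grow without R-spondin, the Wnt agonist that was withdrawn here to select them. RNA was taken 7 or 20 days after tamoxifen was added, with 4 samples at each time, and each was hybridised to 1 Illumina mouse beadchip array. The comparison asked how expression in the selected cultures at day 20 differed from that at day 7. No undeleted culture was among the samples, so time since deletion, time without R-spondin and time in culture moved together. Signal of sex-linked genes, described below, also differed in part between the days, so that difference is partly confounded with time. The labels do not say whether the 4 samples of a day came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

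All 8 arrays held 45281 probes with a median normalized log2 intensity of 6.81, and between 52.99% and 53.17% of probes lay above the background limit of 6.796. Over the 12466 genes tested, 1 probe each, the first principal component carried 53.04% of the variance and separated the days. Day 7 replicate 2 stood apart within its day, with a Pearson r across these genes of 0.9725 to 0.9797 against the other day 7 arrays (genes are not independent replicates). Xist, the X-inactivation transcript of female cells, was at 9.39 to 10.41 on 6 arrays by its brightest probe, which was below the limit on day 20 replicates 1 (6.68) and 4 (6.74); of its 3 other probes, 1 was at 6.80 on day 20 replicate 4, just above the limit. The Y-linked gene Eif2s3y was at 8.34 and 8.51 on those arrays, and at 6.66 to 6.73 on the other 6. No day 7 array showed this pattern of Xist and Eif2s3y, so it was not balanced between the days. Over all tested genes, day 20 replicates 1 and 4 correlated at r = 0.9917 and replicates 2 and 3 at 0.9905. Between these pairs r was 0.9827 to 0.9846. The day 20 arrays thus fell into pairs along with Xist, whereas limma took them as 4 alike replicates. Values on the 6 arrays with Xist signal stand beside the results they alter, as a check chosen after the data were seen, as was a check with the background mode subtracted, whose values for genes near the limit are set in part by its offset of 16.

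Between the days, 604 of 12466 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 313 of them higher and 291 lower at day 20. Large falls included those of Zg16, Apoa1 and Sis, and large rises those of Sftpd, Car9 and Egln3. At least 2-fold changes numbered 77 upward and 85 downward, and at least 4-fold changes 14 and 32. Groups did not overlap for 603 of the 604 genes, and for 13.11% of all genes tested against 2.857% by chance. The median log2 fold change of all tested genes was 0.005. The count fell to 301 without day 7 replicate 1, 349 without day 7 replicate 3, 373 without day 20 replicate 2 and 353 without day 20 replicate 4. The higher genes numbered 200 without day 7 replicate 4, and the lower genes 177 without day 20 replicate 1. On the 6 arrays with Xist signal it was 413, with 272 higher and 141 lower, so the share of higher genes was 65.86% in place of 51.82%.

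**Figure D1:**
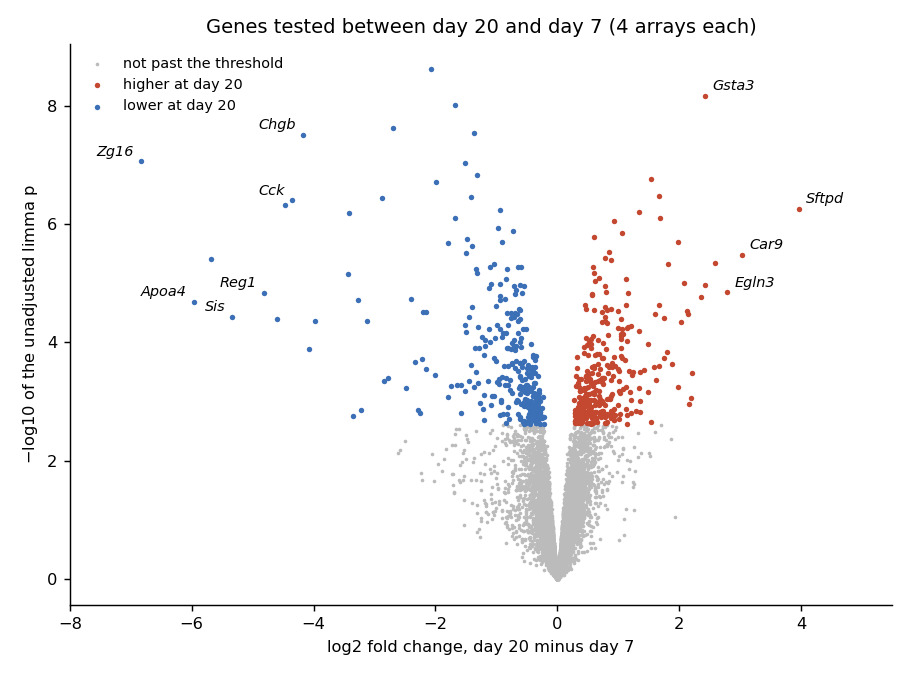
Each point is 1 of the 12466 genes tested, with the log2 fold change (day 20 minus day 7, 4 arrays each) on the x axis and minus log10 of the unadjusted limma p on the y axis. The 313 genes higher at day 20 are red and the 291 lower are blue; Zg16 lies farthest left at -6.83 and Sftpd farthest right at 3.96.

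Apc itself gave 7.28 ± 0.14 at day 20 and 7.35 ± 0.12 at day 7 (SD, n = 4 each; limma adjusted p = 0.71). Both days followed the deletion and the position of the probe relative to the deleted exon was not known, so this value checks nothing about the labels.

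Enteroendocrine genes, which mark the hormone-secreting cells of the gut, fell almost throughout: 19 of 21 tested members were lower at day 20 and none was higher (20 lower when adjusted over the list alone). Chgb, a granule protein, fell by 4.17 on the log2 scale (SE 0.21, limma adjusted p = 6.44e-05), from 11.24 ± 0.34 to 7.07 ± 0.36 (SD, n = 4 each). The glucose-dependent insulinotropic peptide gene Gip fell by 2.70, the prohormone-processing enzyme gene Cpe by 1.68, and Insm1, a transcription factor of the lineage, by 1.52 (3 day 20 arrays above background); with the background mode subtracted Gip was at -4.32 and Insm1 at -3.17. Ghrl, encoding ghrelin, fell by 4.47, with 3 day 20 arrays above background. Cck and Sst, encoding cholecystokinin and somatostatin, were not above background on any day 20 array; they were at least 19.7-fold and 10.1-fold lower there (limma adjusted p = 0.000328 and 0.00173). Chga, encoding chromogranin A, also fell (limma adjusted p = 0.000219), but the probe tested was above background on no day 20 array, and each of 2 other probes on 1, so its size is not given. The camera adjusted p was 1.56e-34 with the preset correlation and 0.0067 with an estimated correlation, and the list median was -1.52, also with 5 members taken at their bounds (-3.17 with the background mode subtracted).

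Absorptive enterocyte genes were lower in 7 of 24 tested members (11 when adjusted over the list alone), and none was higher. The apolipoprotein gene Apoa1 fell by 5.68 on the log2 scale (SE 0.53, limma adjusted p = 0.00129), the brush-border disaccharidase gene Sis fell by 5.34 and Apoc3 fell by 4.60, with 1 day 20 array above background for Apoc3, so background limits that size. Sis was at 6.94 to 7.03 on the day 20 arrays, near the background limit, so background limits the size of its fall too. Apoa4 also fell (limma adjusted p = 0.00322), but the probe tested was above background on no day 20 array, so its size is not given; another of its 3 probes, above background on 3 day 20 arrays, differed by -2.98. Alpi, the intestinal alkaline phosphatase gene, differed by -0.98 without passing (adjusted p = 0.18), with 2 day 20 arrays above background; it passed at -0.55 without day 7 replicate 2 (0.0152), and with the background mode subtracted (0.0228). Across the list the median was -1.13 (camera adjusted p = 4.95e-09; adjusted p = 0.39 with an estimated correlation), and -1.96 with the background mode subtracted. Day 7 replicate 2 had the highest list score, 2.14 against 0.249 to 0.557 on the other day 7 arrays and -0.908 to -0.828 at day 20; without it the list median was -0.59.

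Goblet cell genes, those of the mucus-secreting lineage, were lower in 4 of 14 tested members (10 when adjusted over the list alone). Zg16, a secreted lectin-like protein, fell from 13.60 ± 0.93 to background (6.77 ± 0.06; SD, n = 4 each; limma adjusted p = 0.000145), with 1 day 20 array above the limit, so background bounds the measured difference of -6.83. Muc2, the main intestinal mucin, fell by 3.12, Clca1 by 2.23 and the trefoil factor gene Tff3 by 0.89. The median over the list was -0.74 (camera adjusted p = 8.09e-07; adjusted p = 0.12 with an estimated correlation). On all 8 arrays with no filter on dim probes the median was -0.30. On the 6 arrays with Xist signal it was -0.46, and Clca1 (adjusted p = 0.073) and Tff3 (0.19) no longer passed. Tff3 also missed the threshold without day 7 replicate 3 (0.088), day 7 replicate 4 (0.056) or any 1 of day 20 replicates 1 (0.094), 2 (0.085), 3 (0.06) and 4 (0.094), under cyclic loess (0.052) or with no filter (0.06). With the background mode subtracted Clca1 was at -3.91.

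Other large falls lay outside these lists or in smaller ones. Guca2b, encoding the peptide uroguanylin, fell by 3.97 and Scin, encoding the actin-severing protein scinderin, was at least 16.4-fold lower; on the 6 arrays with Xist signal Scin had an adjusted p of 0.064. Of 4 tested members of the Reg family of secreted lectins, Reg1 fell by 4.81 and Reg3a by 2.41 while Reg3g, above background on 3 day 7 arrays, rose by 1.69 (3.14 with the background mode subtracted). Reg3b differed by 1.93 without passing, by 1.03 with probes averaged, 1.01 without day 7 replicate 4 and 2.90 without day 7 replicate 2 (13.76 ± 0.45 against 11.82 ± 2.33, SD, n = 4 each). The family was not called as a list (camera adjusted p = 0.61).

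Of 17 tested genes of crypt base columnar stem cells, 4 were lower (6 when adjusted over the list alone) and none was higher. Slc14a1 fell by 1.52 (limma adjusted p = 0.00527), Rgmb by 1.01 (0.00366), Olfm4 by 1.80 (0.0283) and Lgr5, the receptor that marks these cells, by 0.82 (0.0215). Their median was -0.33 (camera adjusted p = 5.66e-05; adjusted p = 0.19 with an estimated correlation). Ascl2, a transcription factor of the same cells, was at 9.86 ± 0.18 against 9.77 ± 0.19 (SD, n = 4 each; limma adjusted p = 0.75). With probes averaged per gene Olfm4 was at -0.94, where its other probe lay at background (mean 6.77). With the background mode subtracted Rgmb was at -1.79. On the 6 arrays with Xist signal the adjusted p was 0.13 for Lgr5 and 0.094 for Olfm4. For Lgr5 it was 0.056 without day 7 replicate 1, 0.057 without day 7 replicate 4, and 0.054, 0.055 and 0.061 without day 20 replicates 1, 2 and 4; for Olfm4 it was 0.082, 0.075 and 0.07 without day 7 replicates 1, 3 and 4, and 0.069 without day 20 replicate 4.

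**Figure D2:**
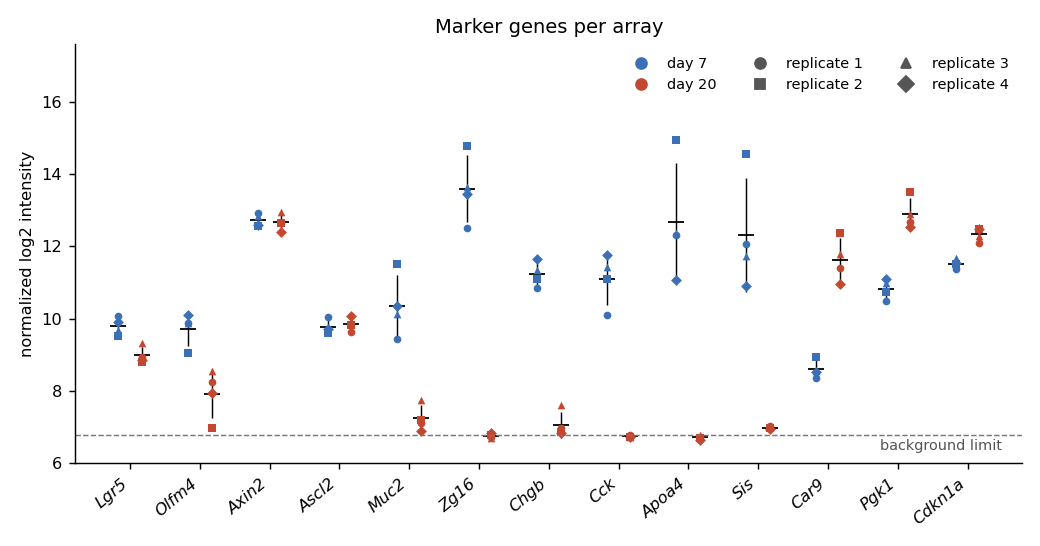
Normalized log2 intensity (y axis) of 13 marker genes (x axis) on each array, day 7 in blue and day 20 in red, with marker shapes for replicate numbers; horizontal bars are means and vertical bars 1 SD (n = 4), and the dashed line is the background limit of 6.796. Axin2 and Ascl2 overlap between days, whereas the probes drawn for Cck and Apoa4 lie below the limit on all 4 day 20 arrays.

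Wnt target genes were not called as a list: 1 of 22 tested members, Lgr5, was lower and none was higher, with the same count when adjusted over the list alone (median -0.03, camera adjusted p = 0.24). Axin2, a feedback inhibitor of the pathway, was at 12.67 ± 0.22 at day 20 and 12.73 ± 0.18 at day 7 (SD, n = 4 each; limma adjusted p = 0.84), with a 95% confidence interval of the log2 difference from -0.36 to 0.23. Cd44 differed by 0.06 (adjusted p = 0.94) and Myc by 0.20 (0.58). These 3 differences, on the 6 arrays with Xist signal, took the opposite sign, at 0.07 for Axin2, -0.175 for Cd44 and -0.0375 for Myc, and none passed. Next by adjusted p among the list's members after Lgr5 were Prox1 at -1.57 (limma adjusted p = 0.11), Ephb3 at -0.165 (0.13) and Notum at -1.525 (0.15). None of them passed, although Prox1 did in 1 of 17 alternative settings (0.0468). On the 6 arrays with Xist signal Prox1 was at -0.67 and Notum at -0.57. Day 20 replicates 1 and 4, the arrays with Xist near background, had Wnt list scores of -0.27 and -0.56, against 0.11 and 0.21 on day 20 replicates 2 and 3. Paneth cell genes, of the antimicrobial crypt-base lineage, also scored lower on those arrays, with -0.675 and -1.01 against 0.109 and 0.567. That list had 1 higher member of 13 tested, the matrix metalloproteinase gene Mmp7 (log2 change 0.83, adjusted p = 0.0164, 3 day 7 arrays above background), and none lower (1 higher and 1 lower when adjusted over the list alone). The camera adjusted p of 0.0576 became 0.0228 without day 7 replicate 4, 0.0394 and 0.000829 without day 20 replicates 2 and 3, 0.0392 with no filter, 0.0242 with an intensity trend and 0.0278 with the background mode subtracted, all toward lower values. Mmp7 had an adjusted p of 0.052 without day 7 replicate 1 and a change of 2.13 with the background mode subtracted. Lyz1, encoding Paneth cell lysozyme, differed by -1.06 (adjusted p = 0.29), by -0.68 without day 20 replicate 4 (0.49) and by -0.25 on the 6 arrays with Xist signal (0.84). On the 6 arrays with Xist signal the Wnt and Paneth score differences became 0.03 and 0.09, from -0.26 and -0.51 on all 8. The Wnt difference was also -0.111 without day 20 replicate 4, and the Paneth difference -0.306 without day 7 replicate 1, -0.779 without day 20 replicate 3 and -0.252 without day 20 replicate 4.

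Genes of glycolysis rose: 11 of 16 tested members were higher at day 20 and none was lower (14 when adjusted over the list alone). Pgk1 rose by 2.08 on the log2 scale (SE 0.22, limma adjusted p = 0.00223), Aldoa by 1.68, Pfkl by 1.67 and Pkm by 0.88. With probes averaged per gene Pgk1 was at 1.08 and Pfkl at 0.98, where the other probe of each was dim (means 6.90 and 7.165). The list median was 0.915 (camera adjusted p = 2.49e-14; adjusted p = 0.11 with an estimated correlation). Genes induced under low oxygen rose in 7 of 13 tested members and none fell (12 higher when adjusted over the list alone). Car9, a carbonic anhydrase, rose by 3.04 (SE 0.28, limma adjusted p = 0.00117), the prolyl hydroxylase gene Egln3 by 2.79, Pdk1, a kinase that restrains pyruvate oxidation, by 2.03 and the glucose transporter gene Slc2a1, which both lists hold, by 1.11. With probes averaged per gene Egln3 was at 1.52 and Pdk1 at 1.198, where the other probe of each was dim (means 6.90 and 7.17). The hypoxia median was 1.11 (camera adjusted p = 1.55e-11; adjusted p = 0.17 with an estimated correlation). Hypoxia scores were 0.205 and 0.546 on day 20 replicates 1 and 4 and 1.21 and 0.868 on replicates 2 and 3. Oxidative phosphorylation had no changed member among 33 tested (camera adjusted p = 0.43; median 0.03).

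Cholesterol biosynthesis genes were higher in 9 of 18 tested members and none was lower (14 higher when adjusted over the list alone). Mvd rose by 1.07 (SE 0.14, limma adjusted p = 0.00569), Lss by 0.88, Msmo1 by 0.84 and Dhcr7 by 0.57. The single other probe of Lss, dim at a mean of 7.00, was almost unchanged (-0.03), and the average over both was 0.43. Across the list the median was 0.54 (camera adjusted p = 1.19e-11; adjusted p = 0.12 with an estimated correlation). Scd1, a fatty acid desaturase outside the list, rose by 2.21 (limma adjusted p = 0.0164; 0.054 without day 7 replicate 1).

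Inflammatory and NF-kB response genes were higher in 9 of 20 tested members and none was lower (15 higher when adjusted over the list alone). Tnfaip2 rose by 2.14 (SE 0.27, limma adjusted p = 0.00407), the acute-phase gene Saa3 by 0.85, the adhesion molecule gene Icam1 by 0.68 and the chemokine gene Cxcl2, above background on 3 day 7 arrays, by 0.52. Lcn2, an iron-sequestering antimicrobial protein above background on 2 day 7 arrays, rose by 2.20 (adjusted p = 0.0286) but missed the threshold without day 7 replicate 1 (0.072), 2 (0.054), 3 (0.072) or 4 (0.069) or day 20 replicate 2 (0.07). Cxcl2 had an adjusted p of 0.05048 on the 6 arrays with Xist signal. With the background mode subtracted Saa3 was at 2.15, Icam1 at 1.13, Cxcl2 at 1.55 and Lcn2 at 3.90. Over the list the median was 0.49 (camera adjusted p = 5.55e-10; adjusted p = 0.0067 with an estimated correlation), 0.78 with the background mode subtracted and 0.32 with no filter. Interferon response genes were not called as a list (camera adjusted p = 0.21). Of 27 tested members 1, the class I light chain gene B2m, fell by 0.80 (limma adjusted p = 0.0343), with the same count when adjusted over the list alone. B2m missed the threshold without day 7 replicate 1 (0.069) or 4 (0.068), without day 20 replicate 1 (0.075), 2 (0.075), 3 (0.059) or 4 (0.086), under cyclic loess (0.052), with no filter (0.05044) and on the 6 arrays with Xist signal (0.16).

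Genes regulated by p53 or tied to senescence were higher in 6 of 19 tested members and none was lower (8 higher and 1 lower when adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a rose by 0.82 (SE 0.11, limma adjusted p = 0.0049), Ccng1 by 1.01 and Trp53inp1 by 0.55. The median was 0.33 (camera adjusted p = 5.66e-05; adjusted p = 0.17 with an estimated correlation). Cdkn2a differed by 0.28 without passing (adjusted p = 0.062), but passed with an intensity trend (0.0213), with array weights (0.0466) and with the background mode subtracted (0.92, adjusted p = 0.0155). Ccng1 had an adjusted p of 0.089 on the 6 arrays with Xist signal and 0.051 with probes averaged per gene. The list of unfolded protein and amino acid stress genes had 3 higher members of 22 tested and none lower (6 higher and 1 lower when adjusted over the list alone): Trib3 by 0.80, Sdf2l1 by 0.75 and Chac1 by 0.55 (camera adjusted p = 0.000119; adjusted p = 0.096 with an estimated correlation). With probes averaged per gene Trib3 was at 0.42. Sdf2l1 missed the threshold without day 7 replicate 1 (0.067) or 3 (0.061), without day 20 replicate 2 (0.052) and on the 6 arrays with Xist signal (0.064). Chac1 missed it without day 7 replicate 3 (0.057) or 4 (0.053), without day 20 replicate 2 (0.052) or 4 (0.058) and on those 6 arrays (0.076). Proliferation genes had no changed member among 27 tested or when adjusted over the list alone (median 0.09, camera adjusted p = 0.14, with 0.037 toward higher values with no filter and 0.00966 without day 7 replicate 4). The smallest limma adjusted p was 0.063, for Rrm2, which passed without day 7 replicate 4 (0.0348).

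**Figure D3:**
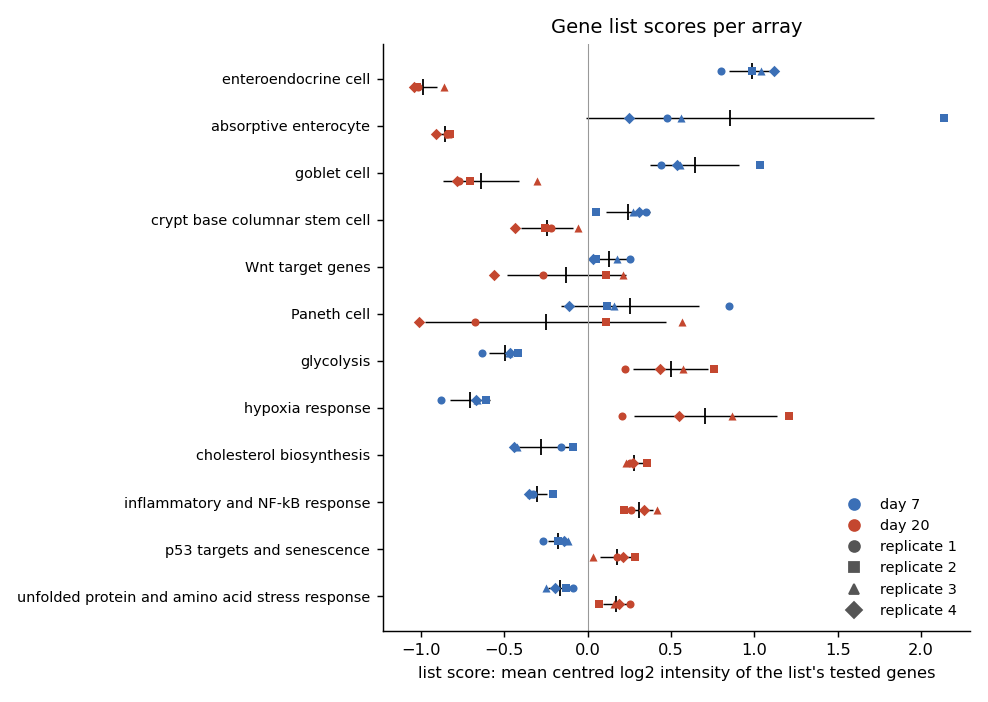
List score per array (x axis: mean centred log2 intensity of the list's tested genes) for 12 gene lists (y axis), day 7 in blue and day 20 in red, with shapes for replicate numbers; black bars are means ± 1 SD (n = 4). Enteroendocrine scores lie between 0.799 and 1.12 at day 7 and between -1.04 and -0.864 at day 20, while Wnt and Paneth scores overlap between days.

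List scores of all 10 called lists separated the days completely. The exact two-sided permutation test gave p = 0.02857 for each, the smallest that 70 arrangements of 8 arrays allow, and 0.0648 after adjustment over the 34 lists, so none passed the threshold by this test. The ileal enterocyte, fibroblast, endothelial, stomach and colon, and reference gene lists, which camera did not call, had the same exact permutation p.

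Among single genes with the largest rises, Sftpd, a collectin of mucosal surfaces, went from 6.88 ± 0.06 to 10.84 ± 0.67 (SD, n = 4 each), a rise of 3.96 (SE 0.29, limma adjusted p = 0.000401). Its day 7 values, 6.81 to 6.93, lay near the background limit, so background limits that size. Across 17 alternative settings it ranged from 3.41 to 5.892. Hgfac, encoding a protease that activates hepatocyte growth factor, rose by 2.58, Mgarp by 2.43 and Stc2 by 2.13. Mgarp was above background on 3 day 7 arrays, and with the background mode subtracted it was at 4.35. Isx, an intestinal homeobox gene, rose from background at day 7, where 1 array was above the limit, so background bounds its measured difference of 2.36 (adjusted p = 0.00283). Serpinb11 rose by 2.17 (adjusted p = 0.0321) but not without day 7 replicate 2 (0.053), 3 (0.081) or 4 (0.073), without day 20 replicate 3 (0.06) or 4 (0.063), or on the 6 arrays with Xist signal (0.051).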

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

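Of the tests in this part, the count of splits was set before its result was seen; the other tests were chosen after the values they measure had been seen.

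More genes changed between the days than between regrouped arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many changed genes, the real one with 604. The highest other split gave 0. With 35 splits, ranking first is the strongest result possible, so chance is unlikely but not excluded. Every other split put both days on each side, which widens the spread within groups and lowers its count. The count cannot tell time from other differences between the day 7 and day 20 arrays.

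In 306 groups of 4 arrays (named genes and list scores on each day), 15 had 1 array far from the rest by Dixon's criterion. That is about the 1 in 20 that chance gives, so the number shows no excess of single outlying arrays. The criterion cannot flag 2 arrays that differ from 2 others, as in Xist at day 20. The groups also overlap, since named genes are members of scored lists. Day 7 replicate 2 was that array in 5 of them: absorptive enterocyte score 2.14 (others 0.249 to 0.557), ileal enterocyte score 0.935 (0.0478 to 0.0928), xenobiotic and glutathione score 0.954 (-0.0767 to 0.0498), Bco1 at 7.94 (6.87 to 6.98) and Gapdh at 13.67 (13.25 to 13.32). Day 7 replicate 1 had Lyz1 at 14.63 (others 13.65 to 13.81) and Car1 at 6.81 (6.73 to 6.74). Day 7 replicate 4 had Ephb3 at 6.98 (7.12 to 7.14) and Hes1 at 9.81 (10.43 to 10.48). Day 20 replicate 3 had a goblet score of -0.302 (-0.786 to -0.704) and an enteroendocrine score of -0.864 (-1.04 to -1.02). Day 20 replicate 1 had Pcna at 7.6 (7.37 to 7.39) and Il1rn at 10.05 (9.63 to 9.69). Day 20 replicate 4 had Bmp7 at 7.62 (8.21 to 8.29) and Cd3g at 6.73 (6.81 to 6.82).

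The lower enteroendocrine, goblet and enterocyte genes at day 20 were set against the influence of day 7 replicate 2. Without it the list medians were -1.55 for enteroendocrine cells (-1.52 with it), -0.652 for goblet cells (-0.739) and -0.594 for enterocytes (-1.13), and the other 3 day 7 arrays scored above all 4 day 20 arrays in each list. That array therefore cannot account for the falls by itself, although it carried much of the size of the enterocyte fall. Loss of an admixed, unselected epithelium of fixed composition would keep the lineages in 1 ratio; the enterocyte minus enteroendocrine level of the members that fell ranged over 2.98 log2 units between day 7 arrays, but over 1.01 (SD 0.529) without replicate 2, so this cannot be told apart from a loss of differentiated cells among the mutant ones. With no undeleted culture, a biological explanation by time after Apc deletion stays open and untested against time in culture.

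The higher hypoxia and glycolysis genes were set against scaling after the loss of abundant transcripts, which would lift other abundant genes too. Ribosomal protein and oxidative phosphorylation genes had a median change of 0.0275 (upper quartile 0.126) against 1.07 for the hypoxia and glycolysis members, which argues against it. On the 6 arrays with Xist signal the medians were 1.6 for hypoxia (1.11 on all 8) and 1.08 for glycolysis (0.915), so the other 2 arrays do not account for the rise. Culture density and oxygen supply are not given in the labels used here and were not tested.

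Day 20 replicates 1 and 4 differed from the other 6 arrays in Xist and Eif2s3y. RNA from animals of opposite sex is a candidate explanation found from these genes, so they cannot test it. Of 2 probes for other Y-linked genes above the background limit on at least 2 arrays, 1, for Kdm5d, was higher on both arrays (7.16 and 7.14) than on the other 6 (6.71 to 6.83). The other, for Uty, was not (7.00 and 7.11 against 6.87 to 7.09). The Uty probe was above the limit on every array, also where Xist was present, so it cannot tell the arrays apart. It therefore does not count against the explanation. Kdm5d went with the explanation, but 1 dim probe does not settle it, so it stays open. Whether these 2 arrays hold cultures of another organoid line or mislabelled samples is untested, since no day 7 array showed the pattern of these 2.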

How the results depend on the processing

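The 2 alternatives chosen after seeing the data were the background-mode subtraction and the 6 arrays with Xist signal. Not run were no background correction and an offset of 50 (both need the unused table), median scaling (all medians were already equal), the authors' values as an alternative (they became the main values) and chip as a block (no chip is given). No called list and none of the 74 named genes past the threshold changed direction under any alternative run on it; under the 17 settings refitted for each gene, 45 stayed past it and 29 lost it at least once. The 2-fold and 1.2-fold requirements were run on the counts alone. Signal over background limited dim genes: 39 tested genes had no probe above the background limit on any day 20 array and 20 none on any day 7 array, so their folds are bounds.

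Replicate numbers were not shown to pair the samples: same-number deviations correlated at -0.00957 to 0.142, and 4 of 8 samples correlated best with their own number. Whether these values exceed chance was not tested. Numbers 1 and 4 had Xist signal by its brightest probe at day 7 (10.01 and 9.87) and not at day 20 (6.68 and 6.74). Eif2s3y went the reverse way, from 6.68 and 6.73 to 8.34 and 8.51. These values argue against a shared animal or culture for numbers 1 and 4. With the number as a block, 401 genes changed (207 higher), and 344 were shared with the 604. Of the 74 named genes, 15 did not pass with the block. These were Lcn2, Serpinb11, Tff3, Bmp7, Jun, Dusp4, B2m, Chac1, Ccng1, Cyp3a13, Snai2, Laptm5, Tff2, Cdx1 and Zmat3 of the p53 list. Leaving out 1 array gave 301 to 579 changed genes (140 to 251 higher, 161 to 328 lower); why the arrays differed in this was not tested. A 2-fold requirement gave 162 (77 higher, 85 lower) and a test against 1.2-fold 162 (71 and 91), by construction. The 6 arrays with Xist signal gave 413, of which 141 were lower; the cause was not tested. Other settings gave 517 to 737. Called lists numbered 2 with an estimated correlation and 10 to 13 otherwise; Paneth, proximal intestine, proliferation, ileal enterocyte, ribosome biogenesis and 3 lists under fry passed in some settings only.

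Directions changed only where nothing was called, and the cause was not tested. As adjusted p, on the 6 arrays: Wnt 0.7553, Paneth 0.9359, tuft 0.9228, BMP and fatty acid oxidation 0.9609, EGFR and oxidative phosphorylation 0.7907. Cell adhesion: 0.976 under cyclic loess, 0.8313 under the strict filter (tuft cells too), 0.9148 with averaged probes, 0.6913 to 0.967 with 1 array left out. EGFR was at 0.9856 and endothelial at 0.9372 with no filter, and ribosomal proteins at 0.938 with array weights. Leaving out 1 array gave EGFR 0.5891 to 0.9682, ribosomal proteins 0.4027 to 0.939, fatty acid oxidation 0.4261 to 0.8573, ribosome biogenesis 0.2492 to 0.9011 and Notch 0.6913 to 0.9072, each with a change of direction for at least 1 array. Xenobiotic: 0.9651 under fry. As log2 changes, Cd44 was -0.1052 with array weights, -0.1567 to 0.25 with 1 array left out and -0.175 on the 6 arrays; Axin2 was -0.16 to 0.02333 with 1 array left out and 0.07 on the 6 arrays, where Myc was -0.0375. List score differences that moved by more than the replicate spread on the 6 arrays were Wnt 0.03227, Paneth 0.08558, ribosome biogenesis -0.2065, BMP -0.009091, EGFR 0.05767, hypoxia 1.744 and stomach and colon 0.2335.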

Other observations

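Genes of drug and glutathione metabolism went both ways: 3 of 23 tested members rose and 3 fell. The glutathione transferase gene Gsta3 rose by 2.42 (limma adjusted p = 4.03e-05) and the heme oxygenase gene Hmox1 by 1.01 (0.0241), while the cytochrome P450 genes Cyp3a13 and Cyp2c65 fell by 2.49 (0.0225) and 2.33 (0.0132). Averaged over its probes Gsta3 was at 1.40. The list was not called (camera adjusted p = 0.24; 4 higher and 8 lower when adjusted over the list alone), and fry gave the opposite direction. Hmox1 missed the threshold without day 7 replicate 1 (0.066), 3 (0.061) or 4 (0.058) or day 20 replicate 2 (0.058) or 4 (0.057). Cyp3a13 missed it without day 7 replicate 3 (0.057) or day 20 replicate 2 (0.059), 3 (0.055) or 4 (0.059), and on the 6 arrays with Xist signal it was at 0.062 and Cyp2c65 at 0.071. With probes averaged Cyp2c65 was at -1.61 (0.068), and with the background mode subtracted Hmox1 was at 1.98. Among EGFR and MAPK feedback genes, Dusp4 rose by 0.68 and Jun fell by 0.96 of 15 tested (camera adjusted p = 0.83). Single members changed in the Notch list (Jag2 rose by 0.57, camera adjusted p = 0.88) and the BMP and TGF-beta list (Bmp7 fell by 0.84, camera adjusted p = 0.25). The other probe of Bmp7, at a mean of 6.80 near the background limit, was almost unchanged (0.01). Single members also changed in the fetal and regenerating epithelium list (Krt17 fell by 1.37, camera adjusted p = 0.27), the proximal intestine list (Onecut2 fell by 0.61, 0.0576) and the immune cell list (Laptm5 rose by 0.56, 0.24). Tff2 and Cdx1 rose by 0.60 and 0.47 in the stomach and colon list (0.21), and Ocln fell by 0.40 in the cell adhesion list (0.98); Snai2 of that list also fell, but it was above background on 1 day 20 array, so its size is not given. Of 12 tested reference genes, Gapdh rose by 0.70 and Pgk1 by 2.08 while B2m fell by 0.80 (camera adjusted p = 0.11); B2m did not pass under cyclic loess (0.052), and Gapdh did not pass without day 7 replicate 1 (0.062), 3 (0.058) or 4 (0.052).

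Several of these single calls were lost when an array was left out. As limma adjusted p, Dusp4 was at 0.064 to 0.081 without any 1 of day 7 replicates 1, 2 and 3 and day 20 replicates 2, 3 and 4, and Jun at 0.051 to 0.062 without day 7 replicate 1 or day 20 replicate 1 or 4. Krt17 was at 0.054 to 0.063 without day 7 replicate 1 or 3 or day 20 replicate 1 or 4, Onecut2 at 0.052 to 0.071 without any 1 of these or day 20 replicate 2, and Bmp7 at 0.053 without day 7 replicate 1. Laptm5 was at 0.068 to 0.098 and Tff2 at 0.051 to 0.075 without any 1 array but day 20 replicate 1, Cdx1 at 0.052 to 0.092 without any 1 array but day 7 replicate 4, and Snai2 at 0.067 to 0.11 without any 1 array but day 7 replicate 1. On the 6 arrays with Xist signal the adjusted p was 0.13 for Krt17, 0.12 for Onecut2, 0.12 for Jun, 0.16 for Snai2 and 0.16 for Cdx1. Ocln was at 0.051 and Cdx1 at 0.051 with an intensity trend and robust variance, Laptm5 at 0.053 under cyclic loess, Laptm5 at 0.0615 and Snai2 at 0.065 with no filter, and Cdx1 at 0.064 with the background mode subtracted. With that subtraction the log2 changes were larger for Tff2 (1.43), Laptm5 (1.24), Krt17 (-2.50) and Jag2 (1.10), and with probes averaged Bmp7 was at -0.41.

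Adjusted over the list alone, counts differed from those over all genes in the fetal (2 higher, 1 lower), EGFR (2 higher, 3 lower), stomach and colon (3 higher, 1 lower) and reference gene (4 higher, 1 lower) lists, and 1 member passed in each of the ileal enterocyte (lower), fibroblast (lower) and endothelial (higher) lists. Under fry, the fibroblast (0.034), stomach and colon (0.0131) and reference gene (0.00927) lists passed. The median and mean differed in sign for tuft cell (-0.05 and 0.06), Notch (-0.01 and 0.02) and cell adhesion genes (0.02 and -0.07). The proximal intestine list passed, toward lower values, with an adjusted p of 0.014 to 0.0446 without day 20 replicate 3 or any 1 day 7 array, with no filter, with averaged probes, with an intensity trend and with the background mode subtracted; the ileal list passed without day 7 replicate 2 (0.0346) and ribosome biogenesis on the 6 arrays with Xist signal (0.00445, lower).

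No member changed in the reserve stem cell (camera adjusted p = 0.27), tuft cell (0.59), ileal enterocyte (0.25), ribosome biogenesis (0.67), fatty acid oxidation (0.68), ribosomal protein (0.72), fibroblast (0.51) or endothelial (0.73) lists. The fibroblast, endothelial and immune lists had 5, 5 and 7 members tested of 18, 10 and 15 on the array. Of 3951 tested probes without a gene name here, 48 were higher and 37 lower at day 20.

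The 4 day 20 arrays differed along with Xist over the tested genes as a whole, by the correlations given above. Genes given here as instances were chosen after their values were seen. Notum, a secreted Wnt inhibitor, was at 9.55 and 9.2 on replicates 1 and 4 and at 11.37 and 11.19 on replicates 2 and 3. Nkd1 was at 9.33, 8.54, 11.08 and 11.37 in the same order, Vim at 8.74, 7.95, 11.05 and 11.31, and Ang4, a Paneth cell product, at 9.65, 9.56, 11.58 and 12.61.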
